A study of Mus musculus with 7 samples.

How the data were processed

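Mouse endometrial epithelial cells were obtained, per the labels' protocols, by mincing and enzymatic digestion of uteri followed by magnetic selection with an EpCAM antibody. Strand-specific mRNA libraries were made from the total RNA with a KAPA kit, per the labels' protocols. Read length and layout are not given in the sources used here. For each of the 7 libraries the authors deposited a table of STAR gene counts, whole-number counts of reads per gene that are not normalized, in an unstranded, a forward and a reverse-stranded column. Per the submitters' processing notes, reads were trimmed with cutadapt and Trim Galore, checked with FastQC, aligned with STAR to mm10 and compared with DESeq2, without stated versions. The authors also deposited 1 table of their own comparison with log2 fold changes, their standard errors and adjusted p-values for each gene. The mean signal of each gene in that table, an average of DESeq2-normalized counts over the libraries as deposited by the authors, was not used.

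The reverse-stranded counts were used because they held 94.8% to 95.6% of both stranded columns in every library, above the 80% required. The totals of reads that count for no gene stayed out of library sizes and tests. Unmapped reads made up 3.90% to 6.70% of the reads of a library, multimapping reads 8.45% to 11.2%, reads without a gene 10.5% to 14.7% and ambiguous reads 0.827% to 1.29%. Ambiguous reads were higher in mutants (mean 1.17%) than in controls (0.843%), without overlap. Gene reads averaged 12707374 in mutants and 22973520 in controls, and 19914 to 21385 genes against 22865 to 23063 genes had a read. Of 53379 gene IDs in the count tables, 53274 matched GENCODE M21 (GRCm38) after the version was taken off, and symbols, coordinates and gene types come from there.

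Libraries were grouped by genotype from the labels, 4 mutant and 3 control. The mutants are separate mice and the controls pools of mice, so p-values measure the spread between these mice and pools, and the sources used here do not say whether the pools shared mice. Correlations of log2 CPM across genes, which are not independent replicates, ran from 0.811 to 0.961 within mutants, 0.977 to 0.982 within controls and 0.848 to 0.890 between groups. No pair of libraries agreed within sampling noise, the lowest chi-square per degree of freedom being 59.7. The median SD of log2 CPM was 0.519 within mutants and 0.235 within controls.

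Genes were kept with filterByExpr and tested in R 4.3.3 with the quasi-likelihood F test of edgeR 4.0.16 (TMM scaling, genotype as the only term, two-sided), with Benjamini-Hochberg adjustment over 14610 genes and a threshold of 0.05. Fold changes are mutant against control, with standard errors from the same fit. Values in CPM are per 1000000 gene reads. The test was tried on simulated counts for the 14610 genes of this comparison, with 200 genes changed in each of 3 simulations. It recovered 1.49% of 2-fold, 47.3% of 4-fold and 82.3% of 8-fold changes, with a mean of 7 false calls per simulation. A gene that did not pass can therefore still differ, since simulated 4-fold changes were missed more often than found with this number of libraries. The recovery rates need not hold for the real comparison, where 1687 genes passed, because the adjustment is stricter when fewer genes change. The simulation also gave each gene the same dispersion in both groups, with genes independent and no library apart. The real mutants spread more than the controls, so the rate of false calls need not hold either.

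The 38 gene lists, the tests between genotypes, the alternatives other than the 2 named last and the rule for named genes were set before the data were examined, while lists and tests added later are named in the closing section. Named genes were 19 fixed genes, the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 5 CPM, no overlap between groups and a settled symbol that is no pseudogene. To these came, for each list, up to 3 members past the threshold with the largest change and a mean of at least 1 CPM, or the most abundant member where none passed. The 38 lists comprised epithelial, uterine, signalling, metabolic and inflammatory programmes, markers of other cell types, and measures of RNA quality. The 35 lists with at least 5 tested genes were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01, Benjamini-Hochberg adjustment over lists). Camera called 1 list higher and 15 lower. With an estimated correlation it called 0, with 6 at an unadjusted p under 0.05, and fry, which asks whether a list moves one way on balance, called 14. The 14 include the p53 and Notch lists (lower, fry adjusted p = 0.0144 and 0.0248), which camera did not call. They leave out the interferon, glandular, mesothelial and histone lists (fry adjusted p = 0.107, 0.128, 0.0756 and 0.0756), which camera called. Counts adjusted over a list alone use that list's genes only. List calls with a library left out use the preset correlation, and an estimated correlation was not run there.

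Of 842 Reactome sets of 10 to 300 tested genes, shipped with fgsea 1.28.0, camera called 47 higher and 59 lower, and 0 with an estimated correlation (63 at an unadjusted p under 0.05). DESeq2 1.42.0 served as an alternative test and as a check of the counting column. Its log2 fold changes on the reverse-stranded counts lay within 0.05 of those in the authors' deposited table, after the median difference was taken off, for 99.98% of genes, against 78.8% with the unstranded counts. Sequence shared between genes was measured as the percent of a gene's 50-base transcript words found in any other gene. Figures and annotation tables used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

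Alternatives were DESeq2 size factors, upper-quartile and total count scaling, DESeq2 and limma-voom in place of edgeR, other filters on low counts, the unstranded counts, counts thinned to the smallest library, removal of mitochondrial and the 50 most abundant genes, an offset for GC content and gene length, the replicate number as a term, and each library left out in turn. Removal of pseudogenes and list counts without mutant replicate 1 were added after seeing the data.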

Results

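RNA was sequenced from EPCAM-positive endometrial epithelial cells, the cells that line the lumen and glands of the uterus, sorted magnetically from dissociated mouse uteri. The 4 mutant libraries each came from 1 CD-1 mouse aged 120 days that carried Cre recombinase driven by Ltf (lactoferrin) and was homozygous for floxed Brg1. Brg1, encoded by Smarca4, is an ATPase of the SWI/SNF chromatin remodelling complex. The 3 control libraries came from pooled wild-type CD-1 mice and were taken over from an earlier series, and the age of these mice is not given in the sources used here. No set of libraries held both genotypes, so genotype, library set and pooling cannot be told apart in any comparison, and no batch term could be fitted. Reads counted in genes totalled 12436971, 12509578, 12518865 and 13364080 in mutant replicates 1 to 4, and 21686278, 21372036 and 25862245 in control replicates 1 to 3. At this depth 3 reads, the floor used here, correspond to 0.224 to 0.241 counts per 1000000 gene reads (CPM) in mutants and 0.116 to 0.140 CPM in controls, which covers counting error only.

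Smarca4, the targeted gene, was lower in every mutant library. Its level was 87.6, 56.7, 86.9 and 105.4 CPM in mutant replicates 1 to 4 against 263, 245 and 279 CPM in the controls, a 3.12-fold lower level (log2 fold change −1.64 ± 0.23 SE, edgeR adjusted p = 0.00967). Smarca4 (ENSMUSG00000032187.16) lies on chromosome 9 from 21616169 to 21704230 on the plus strand of GRCm38. The counts cover the whole gene and do not separate the deleted part from the transcript that remains. The fall kept its size but not its call when a control library was left out, at adjusted p = 0.0612, 0.0532 and 0.0575 without control replicates 1, 2 and 3, while the other alternatives without a replicate term gave adjusted p from 1.95e-08 to 0.0310. Of the other subunits, the paralogous ATPase Smarca2 (log2 fold change 0.49, adjusted p = 0.266) and Arid1a (−0.00, adjusted p = 0.993) did not pass the edgeR test. The value of Arid1a turned positive under upper-quartile (0.13) and total count scaling (0.35). Over the 25 tested SWI/SNF subunits, 2 were higher and 1 lower, also when adjusted over the list alone. Those higher were Bcl7a (1.49 ± 0.29 SE) and Smarce1 (1.09 ± 0.27 SE; uncertain, with 15% of its 50-base words shared with other genes), and without mutant replicate 1 the number higher was 9. The list was not called (camera adjusted p = 0.0633), but was called higher without mutant replicate 1 (adjusted p = 0.0190).

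The comparison asks which transcripts of the endometrial epithelium differ when Brg1 is deleted there. Of 14610 genes tested, 1687 changed, 784 higher and 903 lower in mutants (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 1290 changed by more than 2-fold, 605 higher and 685 lower. The mutant and control ranges did not overlap for 1686 of the changed genes and for 31.5% of all tested genes, against 5.71% by chance with 4 against 3 libraries. The count moved when any 1 library was left out. It was 4403 without mutant replicate 1, 1009, 629 and 940 without mutant replicates 2, 3 and 4, and 133, 169 and 137 without control replicates 1, 2 and 3. Members of the fixed lists were counted again only without mutant replicate 1, the only removal that raised the count of changed genes. Those list counts therefore do not show what is lost when another library is left out. The median log2 fold change of all tested genes was 0.06, against 0.20 with upper-quartile and 0.41 with total count scaling. The share of changed genes that were higher moved with it, from 46.5% to 62.6% and 80.5%. All fold changes given here are relative to the TMM scaling.

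**Figure D1:**
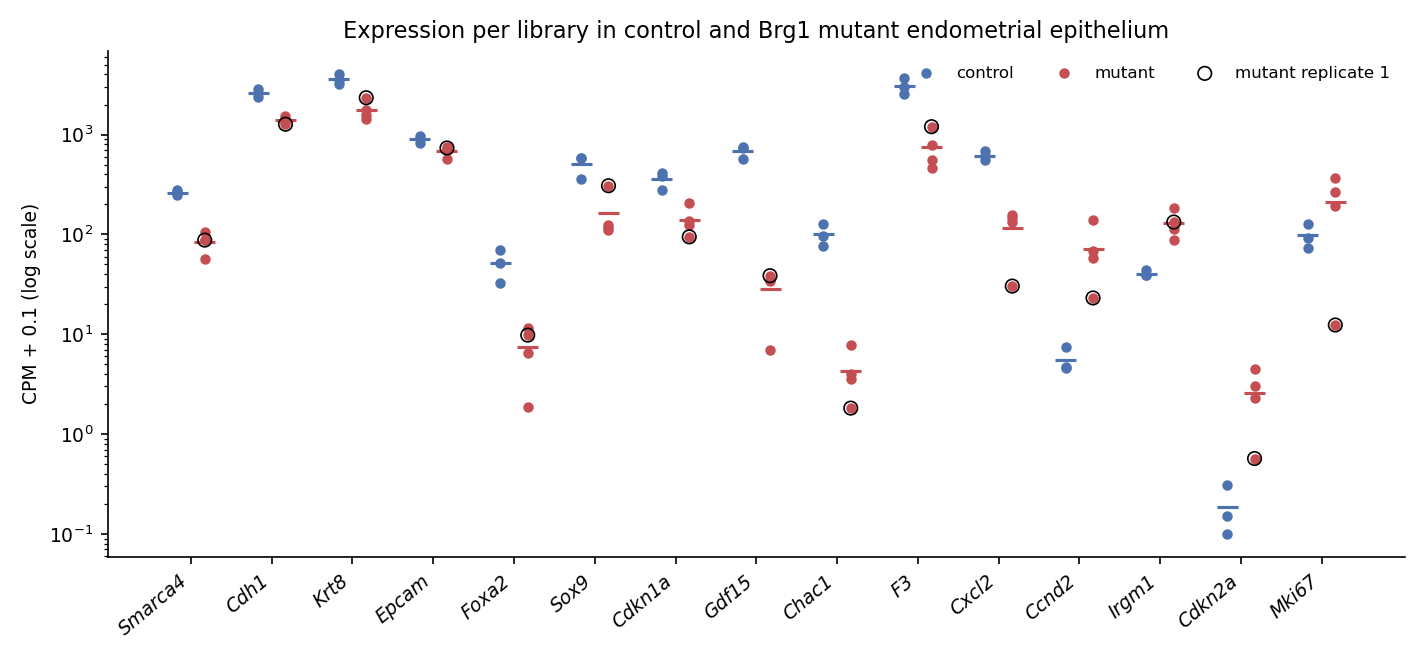
CPM per library on a log axis, with 0.1 CPM added for display, for 15 genes in 3 control (blue) and 4 mutant (red) libraries, where bars mark group means and a ring marks mutant replicate 1. Smarca4 lies at 56.7 to 105.4 CPM in mutants and at 245 to 279 CPM in controls, while Mki67 lies at 12.3 CPM in mutant replicate 1 and above all controls in the other mutants.

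Some genes of epithelial identity were lower in mutants. E-cadherin (Cdh1), the adhesion molecule of adherens junctions, fell from 2622 ± 254 to 1393 ± 119 CPM (SD, n = 3 controls and 4 mutants), a log2 fold change of −0.91 ± 0.20 SE (edgeR adjusted p = 0.0307). Of 38 genes for epithelial junctions and polarity, 9 were lower and none higher (13 lower when adjusted over the list alone). They included the polarity genes Llgl2 (−1.34) and Crb3 (−1.30) and the desmosomal plakophilin Pkp3 (−1.21). The surface antigen used for the sort, Epcam, did not pass the test (−0.38 ± 0.18 SE, edgeR adjusted p = 0.206). Among 17 epithelial regulators, 3 fell and 1 rose (8 lower and 1 higher when adjusted over the list alone). Those that fell were the protease inhibitor Spint1 (−1.43), the transcription factor Ovol1 (−1.18) and the membrane protease Prss8 (−1.08). Of 6 simple epithelial keratins, Krt8 fell (−1.02 ± 0.25 SE, edgeR adjusted p = 0.0421; 2 lower when adjusted over the list alone), and Krt18 had a value of −1.27 without passing. Among 17 squamous and basal genes, 2 fell, Krt4 (−6.20) and Krt6a (−3.44), also when adjusted over the list alone. Krt8 and Krt6a share 26.9% and 45.7% of their 50-base words with other genes, which leaves their counts uncertain. All 4 lists were called lower by camera with a preset correlation (adjusted p = 2.64e-05 for junctions, 0.00505 for regulators, 0.0229 for keratins and 0.00457 for squamous genes). None of the 4 calls held with an estimated correlation (adjusted p = 0.258 for the first 3 and adjusted p = 0.376 for squamous genes with an estimated correlation). Without mutant replicate 1 the numbers lower were 17, 5, 4 and 4.

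No gene fixed for mesenchymal transition passed as higher. Of 36 tested regulators and effectors of epithelial-mesenchymal transition (EMT), 7 were lower (13 lower when adjusted over the list alone; 21 lower without mutant replicate 1). These included the urokinase Plau (−2.95 ± 0.51 SE), the matrix glycoprotein Tnc (−2.22), the integrin Itgb3 (−1.54) and the intermediate filament vimentin (Vim, −0.73 ± 0.17 SE, edgeR adjusted p = 0.0375). Of 29 genes for the basement membrane and its receptors, 3 fell, also when adjusted over the list alone (8 lower and 3 higher without mutant replicate 1). They were plectin (Plec, −1.42), the laminin receptor subunit Itga3 (−1.14) and the laminin chain Lama5 (−1.07). Of 14 Hippo pathway targets, 5 fell (8 lower and 1 higher when adjusted over the list alone; 7 lower and 2 higher without mutant replicate 1), among them tissue factor (F3, −2.05), Amotl2 (−1.63) and Ccn1 (−1.39). Camera called the lists lower at adjusted p = 7.21e-06, 0.00212 and 0.0214, and each had adjusted p = 0.258 with an estimated correlation. Stromal fibroblast markers were also called lower (adjusted p = 0.000336; adjusted p = 0.376 with an estimated correlation), and 1 of them, decorin (Dcn), fell by 1.77 on the log2 scale.

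NF-kB targets were called lower and interferon response genes higher as lists, though neither with an estimated correlation (adjusted p = 0.488 for both). Fry called the NF-kB list (fry adjusted p = 0.0457) but not the interferon list (fry adjusted p = 0.107). Of 26 NF-kB targets and cytokines, 8 were lower and none higher (10 when adjusted over the list alone; 13 without mutant replicate 1). These included the chemokines Ccl20 (−3.68) and Cxcl2 (−2.40, from 614.7 ± 63.1 to 116.8 ± 58.5 CPM) and the cytokine Csf2 (−3.47 ± 0.84 SE). Ccl20 and Csf2 lay between 0 and 2.26 CPM in the mutants. Of 13 complement and acute phase genes, 1 fell, C1s1 (−1.38), also when adjusted over the list alone, and 3 were lower without mutant replicate 1. C1s1 shares 21.8% of its words with other genes and is uncertain. Of 29 interferon response genes, 4 rose and 1 fell (6 and 1 when adjusted over the list alone; 7 and 1 without mutant replicate 1). The apoptosis factor Xaf1 (2.24 ± 0.47 SE) and the GTPase Irgm1 (1.68 ± 0.27 SE) rose, while the antiviral GTPase Mx1 fell (−2.15 ± 0.40 SE). Camera called NF-kB and complement lower and interferon higher (adjusted p = 4.2e-05, 0.0172 and 0.00222), with adjusted p = 0.376 for complement with an estimated correlation. Mutant replicate 1 lay furthest out in the NF-kB list (mean −2.66 relative to the controls, −1.39 to −0.93 in the other mutants) and in the interferon list (1.29, and 0.19 to 0.58). Among 16 genes for MHC class I and antigen presentation, the peptide transporter Tap1 rose (1.30 ± 0.30 SE), also when adjusted over the list alone, and the list was not called (adjusted p = 0.233; 3 higher and 2 lower genes without mutant replicate 1). Immune cell markers were not called (median 0.16, mean 0.05, with the camera test downward at adjusted p = 0.9496), and none of their 25 tested genes passed, while 3 were lower without mutant replicate 1. The pan-leukocyte gene Ptprc had a value of 0.66 and Cd74 of 0.46.

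Some genes set by ovarian steroids and by gland identity were lower. Of 23 oestrogen-induced epithelial genes, 2 fell (1 when adjusted over the list alone; 6 without mutant replicate 1), the transcription factor Cebpb (−2.81 ± 0.22 SE) and the inhibin subunit Inhbb (−1.73). Lactoferrin (Ltf), the gene that drives Cre, lay at 82.7, 2023, 1146 and 1546 CPM in the mutants and at 2940 to 3687 CPM in the controls (−1.42 ± 0.81 SE, edgeR adjusted p = 0.273). Of 15 glandular genes, 2 fell, also when adjusted over the list alone, the gland regulators Foxa2 (−2.81 ± 0.58 SE, edgeR adjusted p = 0.027) and Sox9 (−1.63), and 6 without mutant replicate 1. The list mean per library, relative to the controls, was 0.01 in mutant replicate 1 and −4.79, −4.64 and −2.80 in the others. Smooth muscle and pericyte markers ranked the mutants in the same order (0.24, and −2.02, −1.42 and −1.02), while stromal markers did not (−1.26, and −1.38, −0.50 and −1.64). Both lists were called lower by camera (adjusted p = 0.00101 and 0.0485, with adjusted p = 0.376 and 0.518 with an estimated correlation). The glandular call was lost without mutant replicate 2 (adjusted p = 0.162) and without mutant replicate 3 (adjusted p = 0.0881). Fry did not call the glandular list (fry adjusted p = 0.128). Of 15 progesterone-responsive genes, Sgk1 fell (−1.56) and Fkbp5 rose (0.83), 1 lower and 2 higher when adjusted over the list alone, and 2 lower and 2 higher without mutant replicate 1. Their median was 0.63 and mean 0.22 while the camera test ran downward (adjusted p = 0.681). The median was −0.83 with limma-voom and −1.22 with the replicate number as a term. Among 10 luminal genes Wnt7a rose (1.36), also when adjusted over the list alone (1 higher and 1 lower without mutant replicate 1), and the list was not called (adjusted p = 0.428). Of 19 Müllerian and steroid receptor regulators, 2 rose, among them Pax2 (0.92), and Sox9 fell (2 higher and 2 lower when adjusted over the list alone; 2 higher and 5 lower without mutant replicate 1). Esr1 (0.14) and Pgr (0.80) did not pass. That list had a median of −0.08, a mean of 0.05 and a downward camera test (adjusted p = 0.810), and its median was 0.06 and 0.26 with upper-quartile and total count scaling.

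The mean of the cell cycle list, relative to the controls, was −2.29 in mutant replicate 1 and 1.36, 1.92 and 0.97 in mutant replicates 2 to 4. Mki67, a proliferation marker, stood at 12.3 CPM in mutant replicate 1 and at 269, 369 and 193 CPM in mutant replicates 2 to 4, against 72.6 to 128 CPM in controls (1.11 ± 0.87 SE, edgeR adjusted p = 0.425). Of 40 cell cycle genes, 1 rose, the condensin subunit Ncapg (2.86 ± 0.64 SE), with 0 when adjusted over the list alone, and 25 rose without mutant replicate 1. The list was not called (median 0.98, camera adjusted p = 0.165; adjusted p = 0.906 with an estimated correlation). It was called higher without mutant replicate 1, using the preset correlation (camera adjusted p = 8.63e-10). The correlation estimated between its genes with all libraries was 0.935, far above the preset value, so that adjusted p can overstate the evidence. The removed library was also the only mutant with a list mean below the controls, so the call does not show a rise across all mutants. Among 22 p53 targets and senescence genes, the cyclin-dependent kinase inhibitor Cdkn1a (−1.35 ± 0.29 SE, edgeR adjusted p = 0.0297) and the stress-induced genes Sesn2 (−2.76) and Gdf15 (−4.59) fell. The kinase inhibitor Cdkn2a rose (4.76 ± 1.10 SE) from 0 to 0.211 CPM in controls to 0.469 to 4.41 CPM in mutants, near the floor in controls and in mutant replicate 1 only. The count was 3 lower and 2 higher both when adjusted over the list alone and without mutant replicate 1. Camera did not call the list (median −0.24, or 0.10 with total count scaling, camera adjusted p = 0.0942). It was called lower by camera without mutant replicate 2 (adjusted p = 0.0236) and without mutant replicate 4 (adjusted p = 0.0317). Fry called it lower with all libraries (fry adjusted p = 0.0144). Wnt targets (median 0.41, mean −0.09, test downward, adjusted p = 0.264) and Notch genes (median −0.57, adjusted p = 0.0942) were not called by camera. Fry called Notch genes lower (fry adjusted p = 0.0248). Wnt targets were called lower without mutant replicate 4 (adjusted p = 0.0257), and Notch genes without mutant replicate 2 (adjusted p = 0.0499) and without control replicate 3 (adjusted p = 0.0443). Myc fell (−0.94), 1 of 13 Wnt targets and 0 when adjusted over the list alone, with 2 lower and 2 higher without mutant replicate 1. Of 14 Notch genes, Notch4 (−2.66) and Hey2 (−2.51) fell and Notch3 rose (0.997), with 3 lower and 1 higher without mutant replicate 1 and 5 lower and 1 higher when adjusted over the list alone.

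**Figure D2:**
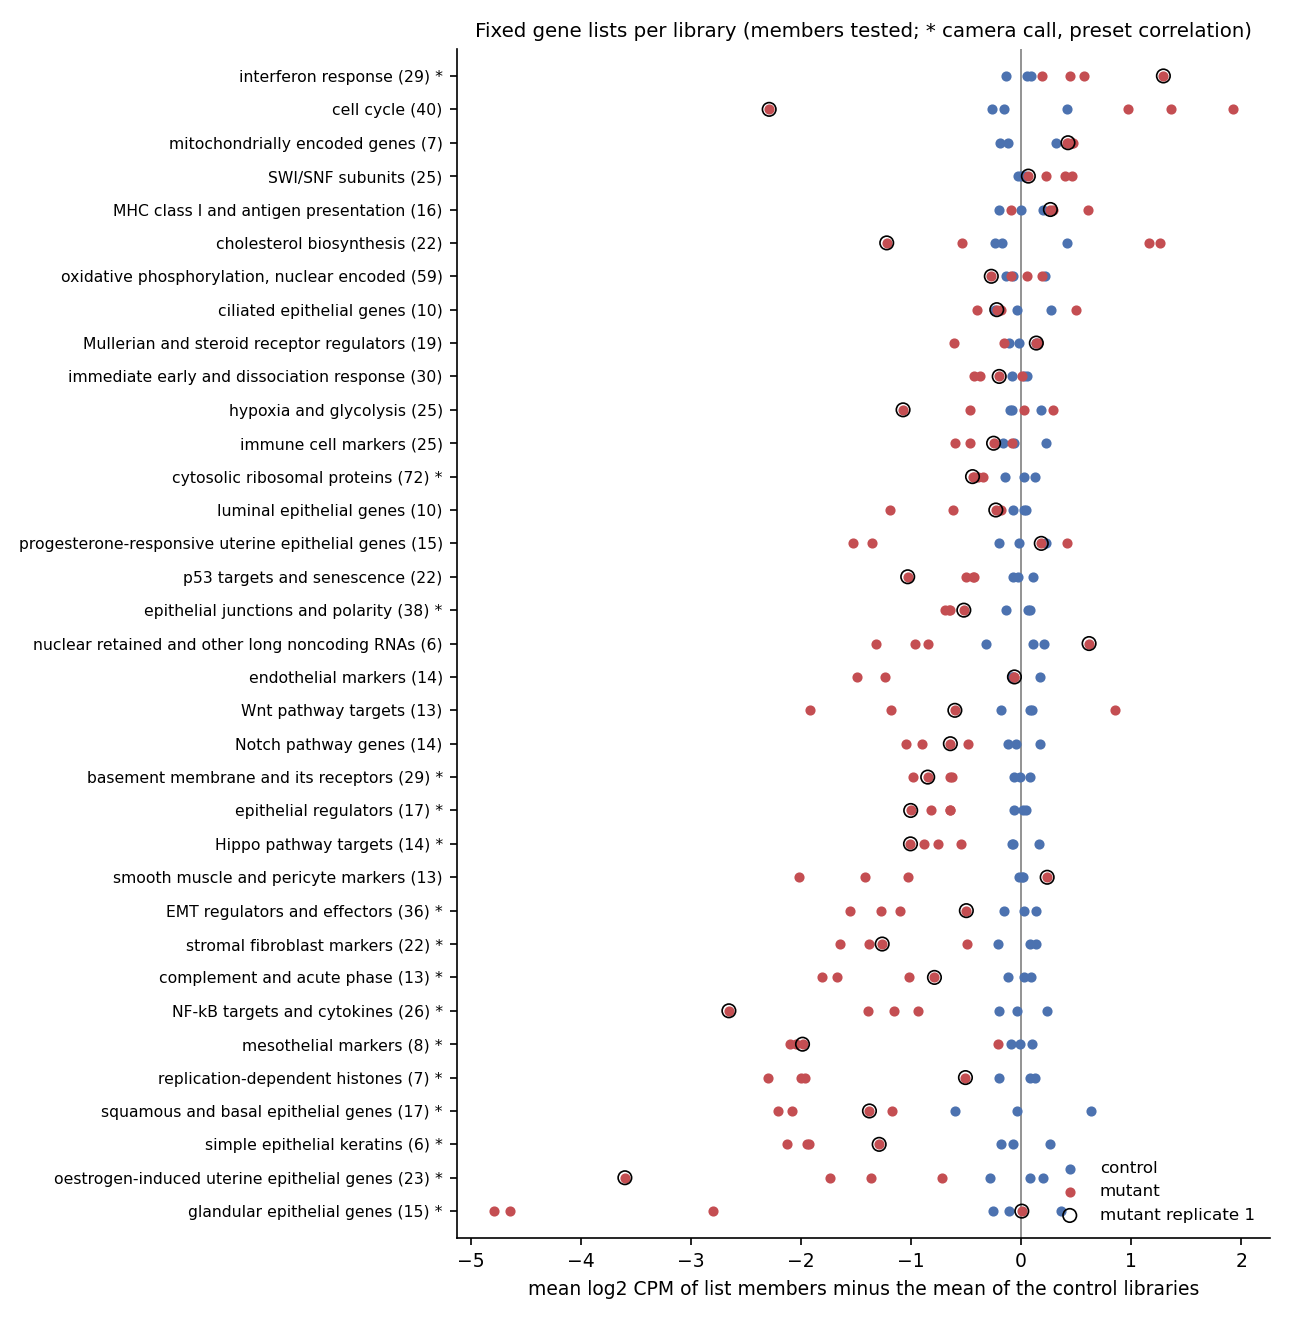
Mean log2 CPM of the tested members of each fixed list per library, minus the mean of the controls, for 3 control and 4 mutant libraries, with the number of members in brackets and an asterisk where camera with its preset correlation called the list. The 4 mutants lie below all controls for junctions (−0.69 to −0.52), while mutant replicate 1 lies apart from the other mutants for cell cycle (−2.29) and glandular genes (0.01).

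Metabolic lists were not called with all libraries. Of 25 hypoxia and glycolysis genes, 2 fell, also when adjusted over the list alone, the angiogenic factor Vegfa (−2.07 ± 0.26 SE) and the glucose transporter Slc2a1 (−1.01 ± 0.17 SE). That list had a median of 0.13, a mean of −0.04 and a downward test (adjusted p = 0.428), and 3 rose and 5 fell without mutant replicate 1. Of 59 nuclear-encoded oxidative phosphorylation genes, Atp5l rose (2.57 ± 0.20 SE) and Ndufb9 fell (−0.94 ± 0.18 SE; uncertain, with 15.6% of its words shared), also when adjusted over the list alone, with 5 higher and 3 lower without mutant replicate 1. The list median was −0.06 (adjusted p = 0.693), and 0.08 and 0.29 with upper-quartile and total count scaling. None of 22 cholesterol synthesis genes passed (median 0.55, adjusted p = 0.592), nor did any of 10 ciliated cell genes (median 0.36, adjusted p = 0.9496), with Cfap43 at −0.72. Without mutant replicate 1 the cholesterol list was called higher (median 0.87, adjusted p = 0.0489), 2 cholesterol genes rose, and 2 ciliated genes rose and 1 fell.

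Markers of non-epithelial cells were called lower for 2 lists, neither with an estimated correlation, and not called for the others. Of 22 stromal fibroblast markers, 1 fell, Dcn (from 128.6 ± 26.7 to 37.8 ± 8.06 CPM), also when adjusted over the list alone (2 without mutant replicate 1), and Col1a1 had a value of −1.41 ± 0.48 SE (edgeR adjusted p = 0.0978). Camera called this list lower (median −1.01, adjusted p = 0.000336; adjusted p = 0.376 with an estimated correlation). The 8 mesothelial markers were called lower too (median −1.15, adjusted p = 0.0101, and adjusted p = 0.488 with an estimated correlation), although none passed. When adjusted over the list alone 0 passed, and Upk3b had −1.21. Fry did not call the mesothelial list (fry adjusted p = 0.0756). Smooth muscle and pericyte markers (median −0.75, adjusted p = 0.102) and endothelial markers (median −0.51, adjusted p = 0.0598) were not called. Both were called lower without mutant replicate 1 (adjusted p = 0.0361 and 0.0489), and endothelial markers also without mutant replicate 4 (adjusted p = 0.0196) and without control replicate 3 (adjusted p = 0.0385). Acta2 had −1.78 and Pecam1 −0.82 without passing. Notch3, also a pericyte marker, and Flt1 (2.32 ± 0.59 SE) rose, but 0 smooth muscle and pericyte markers passed when adjusted over that list alone. Of the endothelial markers 1 was higher and 1 lower both when adjusted over the list alone and without mutant replicate 1. Without mutant replicate 1, 4 smooth muscle markers were lower and 1 was higher, and 1 mesothelial marker was lower. Erythroid, adipocyte and oviduct lists had fewer than 5 tested genes and were not tested as lists. Of 2 adipocyte markers 1 fell, also when adjusted over the list alone (2 without mutant replicate 1), and 1 of 2 oviduct markers fell only without mutant replicate 1. Alas2 (0.46), Pck1 (−1.42) and Ovgp1 (−0.78, with 26.6% of its words shared) did not pass.

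Measures of RNA quality differed between the library sets. The share of gene reads in mitochondrially encoded genes was 2.43 ± 0.251% in mutants (SD, n = 4) and 1.59 ± 0.243% in controls (SD, n = 3), without overlap, and 1 of the 7 tested genes rose, mt-Nd6 (1.96 ± 0.26 SE), also when adjusted over the list alone. The list was not called (median 0.20, camera adjusted p = 0.111), but was called higher without control replicate 1 (adjusted p = 0.0160). Its median was 0.55 with total count scaling. With the unstranded counts mt-Nd6 had −0.13. Of 72 cytosolic ribosomal protein genes, 19 fell and none rose (22 when adjusted over the list alone), led by Rps29 (−1.50 ± 0.15 SE), Rpl13a (−1.40) and Rplp2 (−1.36), with a list median of −0.33 that became 0.02 with total count scaling (camera adjusted p = 7.21e-06; adjusted p = 0.488 with an estimated correlation). These genes share 18.3% to 24.0% of their words with other genes and are uncertain. Replication-dependent histones were called lower (adjusted p = 0.0411; adjusted p = 0.488 with an estimated correlation), with 1 of 7 lower (2 when adjusted over the list alone; 4 without mutant replicate 1) and Hist1h1c at −2.20 (edgeR adjusted p = 0.109). That call was lost without mutant replicate 3 (adjusted p = 0.0555) and without mutant replicate 4 (adjusted p = 0.0748). Fry did not call the histone list (fry adjusted p = 0.0756). Of 30 immediate early and dissociation genes, 3 rose and 5 fell (6 and 9 when adjusted over the list alone; 6 and 11 without mutant replicate 1), with Hspe1 (1.58; uncertain, with 18.4% of its words shared) higher and Ier5 (−1.97) and Ier3 (−1.69) lower. The list was not called (median −0.23, and 0.11 with total count scaling; adjusted p = 0.349), and Fos had 0.31 ± 0.38 SE. None of 6 long noncoding RNAs passed (median −0.36, adjusted p = 0.603), and Malat1 had −0.29, or 0.02 with total count scaling.

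The largest rises and falls among well expressed genes included regulators outside the fixed lists. The cyclin Ccnd2 rose 13.1-fold, from 5.47 ± 1.61 to 71.8 ± 48.3 CPM (SD, n = 3 and 4; edgeR adjusted p = 0.0161), and the cytokine Il18 rose 9.72-fold. The translation factor paralogue Eif5a2 rose 18.6-fold, with 30.7 CPM in mutant replicate 3 and 2.11 to 6.98 CPM in the other mutants. Cntnap2, Fam184b, Nrep, Zfp605, Naip6, Ncapg and Sec61g rose by log2 fold changes of 2.83 to 3.24. The stress-induced cytokine Gdf15 fell 24.1-fold, from 690.2 ± 104 to 28.6 ± 14.6 CPM (edgeR adjusted p = 0.00712), and Chac1, a glutathione-degrading enzyme, fell 23.9-fold (edgeR adjusted p = 0.00509). The nuclear receptor Nr0b2 (−6.24), the deiodinase Dio3 (−5.34), the transcription factor Foxn1 (−5.09) and the surface protein Cd109 (−4.72) also fell, each to at most 3.30 CPM in any mutant library. Ceacam2 (−7.42) fell too, but shares 47.0% of its words with other genes, and Naip6 and Sec61g share 21.5% and 14.8%, so their counts are uncertain. The counts of n-R5-8s1 (−8.17) and Mir6236 (−4.64) are uncertain for another reason, as they varied from 7.97 to 294 CPM and from 323 to 1150 CPM among the controls. Both lie in repeated ribosomal sequence, although the measure of shared words gave 0% for each. Of the 78 named genes past the threshold, 78, 52, 34 and 43 still passed without mutant replicates 1 to 4, and 16, 17 and 16 without control replicates 1 to 3, while 77 or 78 had the same direction.

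**Figure D3:**
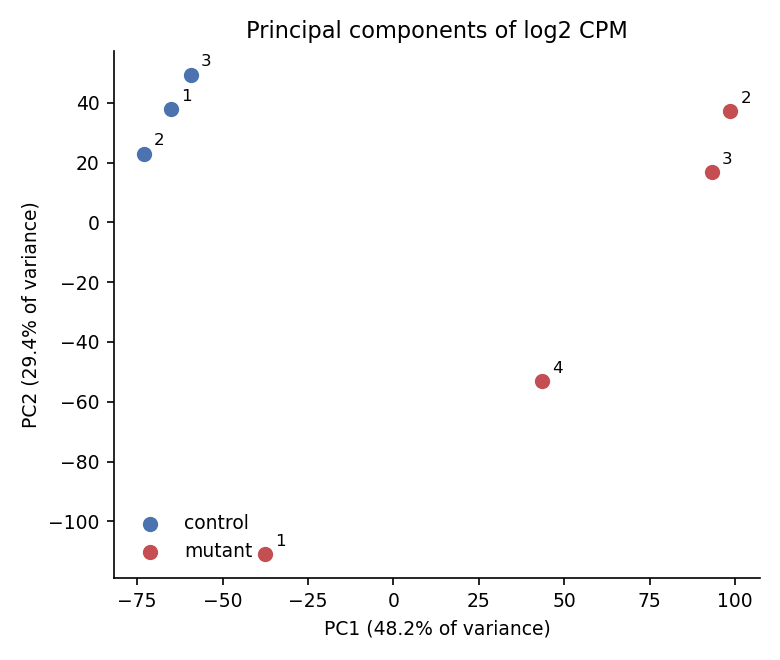
First 2 principal components of log2 CPM, with 48.2% and 29.4% of the variance, for 3 control (blue) and 4 mutant (red) libraries, numbered by replicate. The controls lie between −73.1 and −59.3 on the first component, mutant replicates 2 to 4 between 43.4 and 98.7, and mutant replicate 1 at −37.6, with −110.9 on the second.

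The authors' deposited table holds 23282 genes and calls 1601 higher and 1508 lower at an adjusted p under 0.05. Of the 14479 genes in both tables, the edgeR test called 1667, while 2864 were called in the authors' deposited table. In all, 1564 were called in both with the same direction, which is 93.8% of the edgeR calls and 54.6% of those in the authors' deposited table, and 0 were called in opposite directions. For Smarca4 the authors' deposited table gives a log2 fold change of −1.63 and for Cdh1 −0.90. Some named genes past the edgeR threshold are not called there. Among them are Vim (DESeq2 adjusted p = 0.132), Slc2a1 (adjusted p = 0.117), Wnt7a (adjusted p = 0.116) and Notch3 (adjusted p = 0.214). Others are C1s1 (adjusted p = 0.111) and Fkbp5 (adjusted p = 0.0853), while Krt4, Krt6a and Ovol1 have no adjusted p there. The fold changes of these genes have the same direction in both analyses. Both analyses use the same libraries, so the overlap compares processing only.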

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

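The tests of labelling, of other cells, of oestrogen action and of other splits of the libraries were chosen only after their results were seen. Among 142 values examined within the 4 mutants, 18 had 1 library far from the other 3 relative to their range, where chance gives about 1 in 20, and 10 of the 18 lay in mutant replicate 1.

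Mutant replicate 1 stood apart from the other mutants, near the controls on the first principal component (−37.6) and far from all libraries on the second (−110.9). Its depth was near that of the other mutants, but other measures of the library were not. Unmapped reads made up 6.70%, the highest of all libraries, against 4.24% to 5.15% in the other mutants. Reads without a gene made up 14.0%, against 10.5% to 11.5% in the other mutants. Whether library quality sets it apart was not tested. A mislabelled control is argued against by Smarca4, at 87.6 CPM in this library against 245 CPM in the lowest control. A lower share of epithelial cells would raise the markers of other cell types alike, but against the mean of the other mutants its smooth muscle list shifted by 1.72 and its stromal list by −0.09, which differ by 1.81 (combined SD 0.78), so added cells of a single type, such as smooth muscle, stay open. A stage of low oestrogen action at collection may account for its oestrogen-induced list of −3.60 against −1.74 to −0.72 in the other mutants, but the labels give no stage of the cycle, so this stays open, as do differences between the mutant mice.

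Several values followed this library. Its smooth muscle list mean, relative to the controls, was 0.24 (−2.02 to −1.02 in the other mutants), and lists of 1 or 2 tested genes lay above the other mutants too, at 2.13 for the erythroid (−2.88 to −0.26), −0.24 for the oviduct (−3.94 to −1.60) and −1.68 for the adipocyte list (−5.73 to −3.64). Higher than in the other mutants were Sox9 at 307 CPM (110.5 to 125 in the others), Spint1 at 300.5 CPM (162 to 185), Hist1h1c at 215 CPM (21.7 to 46.9), Ovgp1 at 122 CPM (3.71 to 7.496), Cfap43 at 120.1 CPM (30.7 to 46.0), Pck1 at 88.5 CPM (0.0767 to 3.72), Alas2 at 6.26 CPM (0.0767 to 1.10) and Nr0b2 at 1.72 CPM (0 to 0.0700). Lower were Sesn2 at 9.54 CPM (18.5 to 19.4) and the mean of the p53 and senescence list, at −1.03 relative to the controls (−0.50 to −0.43).

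Other libraries stood apart in single values. Mutant replicate 2 had Llgl2 at 197.8 CPM (97.9 to 103 in the other mutants), Rps29 at 161 CPM (142 to 144), Vim at 87.9 CPM (68.8 to 70.1) and Gdf15 at 6.83 CPM (33.9 to 38.5). Mutant replicate 3 had Col1a1 at 145.5 CPM (38.1 to 50.1) and Eif5a2 at 30.7 CPM (2.11 to 6.98). Mutant replicate 4 had 13364080 gene reads (12436971 to 12518865) and a mesothelial list mean of −0.21 relative to the controls (−2.10 to −1.99).

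The 7 libraries were also split in all 35 ways into 4 and 3. As many changed genes as between genotypes (1687) came from 2 splits, the real one included, so chance cannot be excluded for this count. The highest other value, 1767, came from setting mutant replicates 2 to 4 against mutant replicate 1 with the controls, and 369 of those genes were also called between genotypes in the same direction. Every further split gave at most 1 changed gene. For genes higher, 2 splits gave as many (784, highest other 988), and for changes over 2-fold 2 splits (1290, highest other 1394), so chance cannot be excluded there either. For genes lower, only the real split gave as many (903, highest other 779), at 1 in 35, the smallest share these splits can give. Direction is arbitrary in the other splits, however, since the group of 3 was always taken as control. The 988 genes counted as higher in the split named above were lower in mutant replicates 2 to 4. Chance therefore cannot be excluded for genes lower either, and leaving out 1 library gave 84 to 2089 lower genes. For lists lower, too, only the real split gave as many (15, highest other 14). For lists changed 6 splits (16, highest other 17), for lists higher 34 (1, highest other 14) and for Reactome sets 19 (106, highest other 283) gave as many, and chance cannot be excluded.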

How the results depend on the processing

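Removal of pseudogenes and list counts without mutant replicate 1 were chosen after seeing the data, the other alternatives before. With 3 control libraries and mutants that differed widely, the calls depend on single libraries more than on depth: counts thinned to the smallest library gave 1468 changed genes against 1687, and leaving out any control gave at most 169. Over the alternatives, named genes kept direction and side of the threshold in 1612 comparisons, lost the call with the same direction in 501, gained one in 23 and turned in 23, and lists did so in 736, 31, 38 and 29. Of the 736, 35 came from limma-voom, whose list test used the same unweighted log2 CPM as the main test. Those 35 could not differ. The cause was not tested for any difference given here unless stated.

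Changed genes numbered 2734 with total count scaling, 3423 with DESeq2 on the same genes, 3290 with its own filtering, 5219 with limma-voom and 1057 without a low-count filter, where more genes are tested. Higher genes numbered 1178 with upper-quartile scaling and, in the order above, 2202, 1789, 1664, 2451 and 355. Lower genes numbered 532 with total count scaling, 1634 and 1626 with DESeq2 and 2768 with limma-voom, and changes over 2-fold 2117, 2187, 2410 and 3294. All 1687 edgeR calls were also DESeq2 calls on the same genes. Lists higher, 1 in the report, were 2 with upper-quartile scaling, a mean of at least 5 CPM, the GC content and length offset or without pseudogenes, 3 with total count scaling, DESeq2's own filtering or no filter, and 0 by fry. With an estimated correlation 0 lists were changed, 0 higher and 0 lower, against 6 at an unadjusted p under 0.05, and 0 Reactome sets, against 63. Reactome sets, 106 in the report, numbered 270 with DESeq2's own filtering, 256 without a filter and 64 with the GC content and length offset. Of limma-voom calls, 52.1% were also in the authors' deposited table, against 93.8% for edgeR.

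Leaving out 1 library at a time gave 133 to 4403 changed genes, 45 to 2314 higher, 84 to 2089 lower and 133 to 2989 changed over 2-fold, the highest without mutant replicate 1 and the lowest without a control. Smarca4 ranged from −1.76 to −1.48, past the threshold without any 1 mutant and not without control replicate 1, 2 or 3. Lists higher ranged from 1 to 4, lists lower from 13 to 17, lists changed from 14 to 21, Reactome sets from 54 to 293, and the share of calls in the authors' deposited table from 57.2% to 98.8%.

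The replicate numbers do not pair the libraries: deviations from the group means correlated at −0.02, −0.36 and 0.16 for numbers 1, 2 and 3, and control replicate 2, for example, correlated more with mutant replicate 1 (0.350). With the replicate block, 2 genes changed, 2 higher, 0 lower and 2 over 2-fold (3052 at an unadjusted p under 0.05), and with the block and the GC content and length offset 0 changed, 0 higher, 0 lower and 0 over 2-fold (2800 at an unadjusted p under 0.05). DESeq2 and limma-voom were not run with the block. Smarca4 was −1.79 and −1.62 in these fits, without passing, and with both terms lists higher were 2 and Reactome sets 57. Alas2 turned with the block (−1.34, and −1.23 with the offset) and Arid1a with both (0.33). Lists whose test turned had medians of −0.049 and −0.017 (oxidative phosphorylation), −0.61 and −0.40 (ciliated genes), 0.22 and 0.13 (immune markers) and, with the offset only, −0.34 (mitochondrial genes).

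Single genes turned as follows. Arid1a, at −0.00, was 0.13 with upper-quartile and 0.35 with total count scaling, 0.028 with limma-voom, 0.011 with a mean of at least 5 CPM, 0.029 with unstranded counts, 0.012 with thinned counts, 0.030 without mitochondrial and the 50 most abundant genes, 0.33 with the GC content and length offset and 0.039 without pseudogenes. Esr1 was −0.20 and Alas2 −1.91 with limma-voom, mt-Nd6 −0.13 with unstranded counts and Malat1 0.019 with total count scaling. Leaving out 1 library at a time, Arid1a ranged from −0.055 to 0.12, Esr1 from −0.22 to 0.30, Fos from −0.064 to 0.52 and Alas2 from −1.47 to 0.86.

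Lists whose test turned were oxidative phosphorylation with upper-quartile (median 0.083) and total count scaling (0.29), and ciliated genes with the same scalings (0.51 and 0.78) and without mitochondrial and the 50 most abundant genes (0.41). Immune markers turned with a mean of at least 5 CPM (0.27), unstranded counts (0.19) and the GC content and length offset (0.23), mitochondrial genes with that offset (−0.24), and long noncoding RNAs with DESeq2's own filtering (−0.29) and without a filter (−0.33). Leaving out 1 library at a time turned some tests, with medians from −0.12 to 0.10 for oxidative phosphorylation, −0.27 to 0.88 for ciliated genes, −0.018 to 0.41 for immune markers, −0.63 to −0.080 for long noncoding RNAs, −0.24 to 0.96 for progesterone-responsive genes, 0.18 to 0.87 for cholesterol synthesis and −0.052 to 0.34 for hypoxia and glycolysis. None of these lists was called in the report.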

Other observations

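The tests of shared sequence, depth and GC content in this part were chosen before their results were seen. The list of stress response genes, the clock genes, and the tests of segregating variants, of handling, of genotype and of genes near Smarca4 were chosen only after the data were seen.

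Some genes driven by ATF4 and CHOP, the transcription factors of the integrated stress response, were lower in mutants. Of 38 such genes, 14 fell, 0 passed as higher and 9 had a positive value, those that fell including the translation repressor Eif4ebp1 (log2 fold change −3.32 ± 0.22 SE, 75.5 to 7.53 CPM), the amino acid transporters Slc38a1 (−2.74) and Slc7a5 (−1.84), the kinase-like Trib3 (−2.53), Ppp1r15a (−1.53) and Atf4 itself (−1.19). Ddit3, the gene for CHOP, did not pass (−1.19, edgeR adjusted p = 0.106), nor did Asns (−1.20, edgeR adjusted p = 0.0504). Mthfd2 (−0.79), Shmt2 (−0.13), Phgdh (−0.11), Psat1 (0.44) and Atf3 (0.70) did not pass either. Of 6 aminoacyl-tRNA synthetases in the list, Cars fell (−1.13), while Sars (0.11), Gars (−0.01), Aars (−0.23), Wars (−0.50) and Nars (−0.79) did not pass. The number lower was 16, 13, 11 and 11 without mutant replicates 1 to 4 and 7, 7 and 8 without control replicates 1 to 3.

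Arntl and Nr1d1, clock genes of opposite phase, were both lower. Arntl, a core activator of the circadian clock, fell from 124 ± 12.0 to 24.7 ± 5.84 CPM (−2.33 ± 0.22 SE, edgeR adjusted p = 0.00372), and Nr1d1, which represses it, fell from 219 ± 35.2 to 56.0 ± 22.8 CPM (−1.97 ± 0.32 SE, edgeR adjusted p = 0.0142). Cry1 fell too (−0.86 ± 0.20 SE), while Per1 (0.99), Per2 (−0.73) and Dbp (−0.19) did not pass. Of 5 genes that peak with Arntl 2 were lower (camera p = 0.0209, p = 0.230 with an estimated correlation), and of 9 that peak opposite to it 1 (p = 0.0898 and 0.403). Without mutant replicate 1 these counts were 4 and 2, without mutant replicate 3 or 4 they were 1 and 1, and without any 1 control 1 and 0. The time of day at collection is not given in the sources used here.

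Reactome sets were tested beside the fixed lists. The extracellular matrix organization set of 194 genes had 16 lower and 2 higher (median −0.59, camera adjusted p = 0.000254), a fall shared with the stromal fibroblast markers (median −1.01), so that it need not be one of the epithelium. The set for cell junction organization had 11 lower of 57 (median −0.50, adjusted p = 0.00246). Those called higher included DNA repair (131 genes, 9 higher and 4 lower, median 0.57, adjusted p = 0.00432) and assembly of the primary cilium (152 genes, 14 higher and 5 lower, median 0.37, adjusted p = 0.00795). With an estimated correlation their adjusted p values were 0.580, 0.616, 0.838 and 0.713.

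The fall of stress response genes is a hypothesis found and tested on the same data (list median −0.87, or −0.74 with upper-quartile and −0.54 with total count scaling, camera p = 7.41e-08, p = 0.00432 with an estimated correlation, fry p = 4.48e-05), and 5 of its 38 genes were in fixed lists. A trend with GC content and gene length is argued against as the whole cause, since with that offset the list median was −0.79. Tissue dissociation and handling may differ between the sets, but the fixed immediate early and dissociation list had a median of −0.23 with genes going both ways, which decides nothing. Since 0 library sets held both genotypes, an effect of the genotype cannot be told apart from one of the set.

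Pseudogenes were called more often than protein-coding genes, 36.8% of 432 (117 higher, 42 lower) against 11% of 13119. Differences in depth and a trend with GC content and length are argued against, since the ratio of the called percents was 3.49 with thinned counts and 3.69 with the offset, against 3.35 without either. Variants segregating among the mutant mice would widen the spread of pseudogenes, and their SD was 0.672 times that of protein-coding genes of like level. The gene types may differ in spread without any variants, so this ratio cannot decide. Variants common to all mutants and absent from the controls would not widen that spread and were not tested. Reads of near-identical copies placed differently in the library sets are a candidate explanation: pseudogenes sharing at least 50% of their words were called 3.04 times as often as those sharing under 10% (45.9% of 218 against 15.1% of 73, Fisher's exact p = 1.54e-06), and protein-coding genes 1.67 times as often (17.8% of 185 against 10.7% of 12059, Fisher's exact p = 0.00378). A part played by genotype cannot be told apart, with 0 library sets holding both genotypes, and differing read lengths were not tested.

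Variants carried along with the floxed allele might put called genes near Smarca4. Of 108 tested protein-coding genes within 10 Mb of it, 8 were called (7.41%, exact upper 95% bound 14.1%), against 11% of the 13011 others (Fisher's exact p = 0.280), so an excess of 1.5 times or more is argued against.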
